A study of Mus musculus with 16 samples.

How the data were processed

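RNA from mouse tibialis anterior was sequenced in bulk in 16 libraries, with 4 in each of 4 groups. The groups were taken from the sample labels, as were age, sex and replicate number. The values are whole-number gene counts as deposited, which the authors made with bcl2fastq, Trim Galore 0.6.10, STAR 2.7.11a and HTSeq 2.0.2 on the GRCm39 build, per the submitters' processing notes. Strandedness and the annotation release used for counting were not given in the sources used here. Reads that HTSeq did not assign to a single gene were kept outside the gene counts, in 5 summary categories that name no gene. These categories stayed out of library sizes and tests, and of all counts they took 1.69 to 2.82% (no feature), 7.52 to 8.7% (ambiguous) and 8.3 to 14.41% (not unique). Gene counts per library ranged from 16213335 to 23732277, and 12.2 to 22% of them fell on the mitochondrial genome.

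Gene symbols, transcript length and GC content came from GENCODE M21 on GRCm38, matched by gene identifier. The chromosome and gene order used to count neighbouring genes came from it too, and no coordinates are given because the builds differ. Of 57010 identifiers, 52029 had a symbol, and 13838 of the 14038 genes tested (98.6%) had a length and GC content. Genes that share reads with a near-identical copy, such as Eif3j1 with Eif3j2 and Amd1 with Amd2, have uncertain levels.

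The analysis ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and the figures in Python 3.11.15. The test was edgeR's quasi-likelihood test on the deposited counts, with TMM factors, the default low-count filter over the 4 groups, and 1 model of group and sex for all 16 libraries. It left 11 residual degrees of freedom and a common biological coefficient of variation of 17%. P-values were adjusted by the Benjamini-Hochberg method over the 14038 genes, at a threshold of 0.05. Each knockout was compared with control, the knockouts with each other, and gKO females with gKO males. Females occurred in gKO alone, so the sex term was estimated within that group. Values in CPM, scaled by library size and TMM factor, are shown as mean ± SD, and principal components used log2 CPM with a prior count of 2.

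The 39 gene lists covered muscle programmes, metabolism, matrix, stress, interferon and the clock, and 13 of them held markers of other cell types. They were tested with camera at a preset correlation of 0.01 in the 3 comparisons with control, adjusted over the lists, with an estimated correlation and fry as alternatives. Lists that are not described did not pass camera in those comparisons. The groups, tests, lists, named-gene rule and most alternatives were fixed before the data were examined.

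Named genes were Dock7, and up to 8 of each direction with the largest log2 fold change among genes that passed, had a mean of at least 2 CPM and showed no overlap between the libraries compared. Predicted and clone-named genes were left out of that rule. Further named genes were the 3 members of smallest p of each list called, the 2 most abundant members of marker lists called, and 5 fixed genes of the neuromuscular junction and denervation. For the other 4 comparisons they were the 3 genes of smallest p in each direction. Not every gene that the rule takes is described.

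Replicates were compared pairwise by chi-square, and none agreed within sampling noise, with at least 7.93 per degree of freedom. Overlaps between comparisons were set beside 50 simulations of unchanged groups against the same controls. Alternatives were DESeq2, limma voom with sample weights, other normalization factors and filters, no sex term, the replicate number as a block, other thresholds, only the groups compared, and leaving out each library in turn. Added after seeing the data were a per-library loess offset (span 0.3) on transcript length and GC content, leaving out the library labelled mKO replicate 2 with this offset or in comparisons that do not involve mKO, and an estimated correlation with each library left out in turn.

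The tests were tested on simulated data with 100 genes changed 1.5-fold and 100 changed 2-fold. In the comparisons with control, edgeR recovered 12 and 64 of these for gKO, 31 and 72 for mKO, and 37 and 77 for vKO, with 4, 5 and 8 calls among 13838 unchanged genes. DESeq2 recovered 29 and 74, 51 and 77, and 48 and 80, with 16, 15 and 14 such calls. A changed list was recovered by each set test, and of 30 unchanged lists fry called 1 in mKO and the others called 0. The genes were simulated independently of each other, whereas real lists had estimated correlations as high as 0.82 for ribosomal protein genes in mKO. The simulation therefore does not show how often the preset correlation calls unchanged lists of correlated genes.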

Results

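The transcriptome of the tibialis anterior, a mostly fast-twitch muscle of the mouse lower leg, was profiled by bulk RNA sequencing in mice lacking Dock7 in different cells. Dock7 encodes a guanine nucleotide exchange factor that activates the small GTPases Rac and Cdc42. The 16 libraries fell into 4 groups of 4. Control mice carried the floxed Dock7 alleles without a Cre driver. Deletion was driven by Sox2-Cre throughout the embryo (gKO), by HSA-Cre in myofibres (mKO) or by vChAT-Cre in motor neurons (vKO). Controls, mKO and vKO were males of 4 months, whereas gKO mice were 2 months old, with 2 females and 2 males. Age was therefore confounded with the gKO genotype. The libraries held 16213335 to 23732277 gene counts, with 19112 to 20336 genes detected per library. Nothing in the labels says that replicates came from separate animals, so the p-values measure the spread between these samples.

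Dock7 itself was measured at 5.82 ± 0.585 CPM in control (SD, n = 4), 3.35 ± 0.686 CPM in gKO, 4.3 ± 0.963 CPM in mKO and 6.65 ± 0.265 CPM in vKO. Single control libraries held 5.25, 5.78, 5.63 and 6.63 CPM of Dock7. The gKO libraries held 4.17, 2.67, 2.91 and 3.64 CPM, all below the lowest control. In mKO, replicates 1, 3 and 4 held 4.29, 4.02 and 3.3 CPM of Dock7, whereas the library labelled mKO replicate 2 held 5.61 CPM, inside the control range. The vKO libraries held 7, 6.49, 6.41 and 6.69 CPM of Dock7, a gene measured here in muscle, where motor neuron nuclei are absent. None of these differences passed edgeR's quasi-likelihood test, with log2 fold changes of -0.84 in gKO (adjusted p = 0.117), -0.44 in mKO (adjusted p = 0.139) and 0.19 in vKO (adjusted p = 0.575). With a per-library offset for transcript length and GC content, an alternative added after seeing the data, the vKO value turned to -0.07 (adjusted p = 0.849). With this offset the library labelled mKO replicate 2 was at 2.21 log2 CPM of Dock7. That lay within the other mKO libraries (2.06 to 2.38) and below the lowest control (2.38). Gene counts do not tell a transcript lacking exons from an intact one. The library labelled mKO replicate 2 entered every mKO value given here, and the directions drawn from it carry this limit.

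Apart from the library labelled mKO replicate 2, the groups did not overlap on the first principal component. It held 27.5% of the variance, and its gene loadings followed transcript length with a Spearman rho of -0.61 across genes, which are not independent replicates. Replicates 1, 3 and 4 of mKO lay at 31.9, 39.6 and 44.4 on this component, and the vKO libraries between -32.3 and -22.3. The library labelled mKO replicate 2 lay at -26.4, among the vKO libraries. Its Spearman correlation with the vKO libraries averaged 0.985, against 0.966 with the other mKO libraries. The second component, with 15% of the variance, held the gKO libraries between -37.4 and -22.1 and the other 12 libraries between -8.6 and 21.1. Across genes, the log2 fold change correlated with transcript length at a rho of -0.11 in gKO, -0.4 in mKO and 0.36 in vKO.

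**Figure D1:**
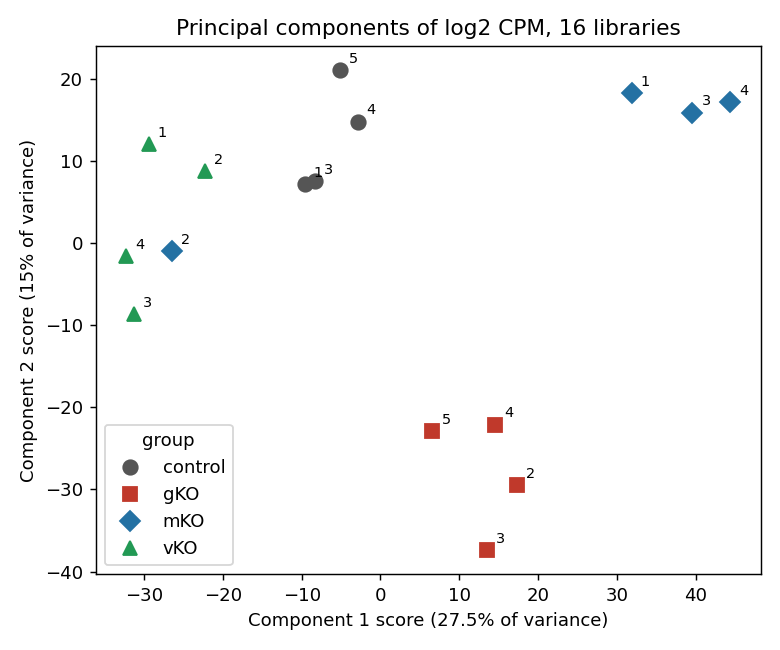
First and second principal components (arbitrary units) of log2 CPM, with 1 point per library coloured by group (4 libraries each). The library labelled mKO replicate 2 lies at -26.4 on the first component, while the other mKO libraries lie between 31.9 and 44.4.

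The gKO muscle was compared with control to find what loss of Dock7 in the whole animal changed in muscle. With sex as a term, the gKO log2 fold changes rest on the 2 male gKO libraries, replicates 4 and 5. The CPM means cover all 4 gKO libraries, so they need not match the fold changes. Interferon-induced GTPases rose, led by Iigp1 at 20.4 ± 21.8 CPM against 5.65 ± 0.481 (log2 fold change 2.49 ± 0.41 SE) and Irgm2 at 34.3 ± 29.5 CPM against 13.8 ± 1.77 (1.89 ± 0.29 SE). Their wide spread came from gKO replicate 4, which held 53 CPM of Iigp1 and 78.3 CPM of Irgm2, against at most 11.6 and 23.4 in the other gKO libraries. Without it the log2 fold changes were 0.85 (adjusted p = 0.845) and 0.76 (adjusted p = 0.54), and neither passed, while without gKO replicate 5 they were 3.23 and 2.51. With the gKO females only they were 0.71 (adjusted p = 0.298) and 0.37 (adjusted p = 0.409). Without the sex term Irgm2 did not pass (1.32, adjusted p = 0.0617), and with the replicate number as a block Iigp1 did not (2.17, adjusted p = 0.0554). Tendon and matrix genes fell: the fibril-organising proteoglycan gene Fmod from 112 ± 50 to 1.5 ± 0.586 CPM (-6.11 ± 1.04 SE), Thbs4, a matrix glycoprotein of tendon, from 132 ± 48.9 to 12.1 ± 4.73 CPM (-3.06 ± 0.51 SE), and the fibril-associated collagen gene Col12a1 from 8.78 ± 4.67 to 0.633 ± 0.243 CPM (-4.14 ± 0.77 SE). The proteoglycan gene Kera fell from 7.56 ± 4.37 CPM in control, and gKO replicate 5 alone had counts, at 0.119 CPM. Actc1, the cardiac actin of developing muscle, rose from 95 ± 28.1 to 501 ± 46.4 CPM (2.31 ± 0.41 SE). These genes passed edgeR's quasi-likelihood test at adjusted p = 0.0156 for Iigp1 and Thbs4, 0.00973 for Irgm2, 0.0163 for Fmod, 0.0201 for Actc1, 0.028 for Col12a1 and 0.0475 for Kera. Without gKO replicate 5 the log2 fold change of Fmod was -6.77 and did not pass (adjusted p = 0.187).

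Further genes passed in gKO. Rian, an imprinted non-coding RNA of the Dlk1-Dio3 cluster, rose by 1.56 on the log2 scale, and the guanylate-binding protein genes Gbp3 and Gbp2 rose by 1.29 and 1.05. Dbp, a clock output factor, rose by 1.12, while the core clock activator Arntl fell by 2.07. The ubiquitin ligase gene Fbxo32 (atrogin-1), a mark of muscle wasting, fell from 307 ± 29.7 to 103 ± 18.2 CPM, with a log2 fold change of -1.57. Ostn, which encodes a peptide secreted by muscle, fell by 1.8 (2.47 without gKO replicate 4, adjusted p = 0.263), Tmem132b fell by 3.76, and Tmem200b rose by 1.14. Eif3j2, one of the pair of near-identical copies that encode the initiation factor subunit eIF3j, fell from 18.8 ± 1.94 to 3.02 ± 0.322 CPM, with a log2 fold change of -2.67 ± 0.15 SE. Its edgeR adjusted p was 8.56e-08, and reads of Eif3j2 and Eif3j1 may be split between the copies. With the gKO females only, Tmem200b (0.42, adjusted p = 0.585), Arntl (-1.39, adjusted p = 0.115) and Gbp2 did not pass. Among the genes of the neuromuscular junction and of denervation fixed for every comparison, Chrna1 (-0.11), Chrne (-0.25), Musk (-0.59) and Myog (0.37) did not pass, and Chrng was too low to test, with 0.403 CPM or less in every library. The sign depended on the setting for Chrna1 (0.45 without the sex term, 0.84 with the gKO females only, 0.04 without control replicate 5 and 0.06 without gKO replicate 4), Chrne (0.21 without the sex term and 0.56 with the females only) and Myog (-0.16 without gKO replicate 4), which did not pass there either.

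Of the 39 gene lists, 15 passed camera with a preset correlation in gKO, and 3 of these also passed with an estimated correlation. The medians and signs of all gKO lists rest on the fold changes of the 2 male gKO libraries. The interferon response list rose, with 25 of 26 measured members positive, a median of 0.66, 3 members called over all genes and 14 adjusted over the list alone (adjusted p = 2.35e-17, and adjusted p = 0.0461 with an estimated correlation). Tendon and muscle spindle markers fell, with all 13 negative, a median of -1.77, and 3 called over all genes and 11 adjusted over the list alone (adjusted p = 1.1e-16, and adjusted p = 0.0429 with an estimated correlation). The denervation response list fell, with 19 of 23 negative, a median of -0.57, and 1 gene, Fbxo32, called over all genes and 3 adjusted over the list alone (adjusted p = 1.68e-05, and adjusted p = 0.0461 with an estimated correlation). Its members with the smallest p after Fbxo32 were the ubiquitin ligase gene Trim63 (-0.57) and the embryonic myosin gene Myh3 (-1.65), which did not pass over all genes. Without gKO replicate 4, the median of the interferon list was 0.35, its called members Iigp1, Gbp3 and Gbp2 did not pass, and the list still passed with the preset correlation (adjusted p = 1.21e-07) but not with an estimated one (adjusted p = 0.199). With an estimated correlation, a test with libraries left out that was added after seeing the data, these 3 lists passed without control replicate 1, and the interferon list also without gKO replicate 5 (adjusted p = 0.0068), where the tendon (0.0873) and denervation (0.181) lists did not. None of the 3 passed with an estimated correlation without control replicate 3, 4 or 5 or gKO replicate 2, 3 or 4, at adjusted p of 0.0539 to 0.199.

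The other 12 gKO lists passed camera with the preset correlation but not with an estimated one, and of these the red blood cell markers also passed fry (adjusted p = 0.0401). Red blood cell markers fell, with 6 of 6 negative and a median of -3.23 (adjusted p = 1.1e-13, and adjusted p = 0.0642 with an estimated correlation), and the globin genes Hbb-bs and Hba-a1 stood at 14.9 and 14.4 CPM against 136 and 110 in control. Fatty acid uptake and oxidation genes, with Acot2 at -0.78 and Plin5 at -0.76, were lower as a list (median -0.34, adjusted p = 7.91e-09, and adjusted p = 0.284 with an estimated correlation). Collagen and matrix genes, with Col12a1, Tnc (-2.74) and Ccn2 (-1.97), were lower (median -0.42, adjusted p = 1.17e-06, and adjusted p = 0.359 with an estimated correlation), with 1 called over all genes and 5 adjusted over the list alone. Immediate early and heat shock genes, with Maff at -1.43, were lower (median -0.54, adjusted p = 6.28e-06, and adjusted p = 0.359 with an estimated correlation). Markers of fibro-adipogenic cells, with Dcn at -0.95 and Gsn at -0.84, were lower (median -0.58, 5 adjusted over the list alone, adjusted p = 1.43e-05, and adjusted p = 0.359 with an estimated correlation). Mitochondrial-genome transcripts (median -0.26, adjusted p = 0.00383, and adjusted p = 0.427 with an estimated correlation), slow fibre genes (median -0.35, adjusted p = 0.0162, and adjusted p = 0.359 with an estimated correlation) and atrophy and autophagy genes (median -0.07, adjusted p = 0.0179, and adjusted p = 0.359 with an estimated correlation) were lower as lists. Markers of neutrophils and mast cells (median -0.76, adjusted p = 0.00929, and adjusted p = 0.359 with an estimated correlation), of Schwann cells and nerve (median -0.48, adjusted p = 0.0108, and adjusted p = 0.427 with an estimated correlation) and of macrophages (median -0.53, adjusted p = 0.0343, and adjusted p = 0.454 with an estimated correlation) were lower as well. Imprinted and early growth genes, among them Meg3 (0.96) and H19 (0.89), which did not pass over all genes, were higher as a list (median 0.26, 1 called over all genes and 3 adjusted over the list alone, adjusted p = 0.0016, and adjusted p = 0.284 with an estimated correlation). 

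Leaving out gKO replicate 5 ended the preset calls of mitochondrial-genome transcripts (0.377), Schwann cell markers (0.0599), slow fibre genes (0.0785) and macrophage markers (0.228). Schwann cell markers were also lost without control replicate 4 (0.165), slow fibre genes without control replicate 1 (0.0834), macrophage markers without control replicate 5 (0.151) or with the library labelled mKO replicate 2 left out of the fit (0.0628), and atrophy genes without control replicate 5 (0.113) or gKO replicate 4 (0.0568).

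In total, 20 genes were higher and 37 lower in gKO than in control among 14038 tested, by edgeR's quasi-likelihood test at an adjusted p of 0.05, with sex as a term. As females occurred in gKO alone, this term leaves the gKO fold to the 2 male gKO libraries, and age stays confounded with it. Without gKO replicate 4 or 5, the fold rests on the lone male left, which is assumed to vary like the other libraries. The 57 genes became 4 without gKO replicate 4 (Eif3j2, and Pla2g4e, Gm14085 and Gm3650, which the fixed rule does not name in gKO and which were named here after their values were seen), 20 without gKO replicate 5, of which 13 were higher and 7 lower, and 27, 35, 25 and 31 without control replicates 1, 3, 4 and 5. Against all 12 libraries of 4-month-old males, 41 genes were higher and 32 lower in gKO. With the library labelled mKO replicate 2 left out of the fit, 447 genes were called. Of the 17 named genes called, Eif3j2 alone passed in each of the 8 fits with 1 library left out.

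**Figure D2:**
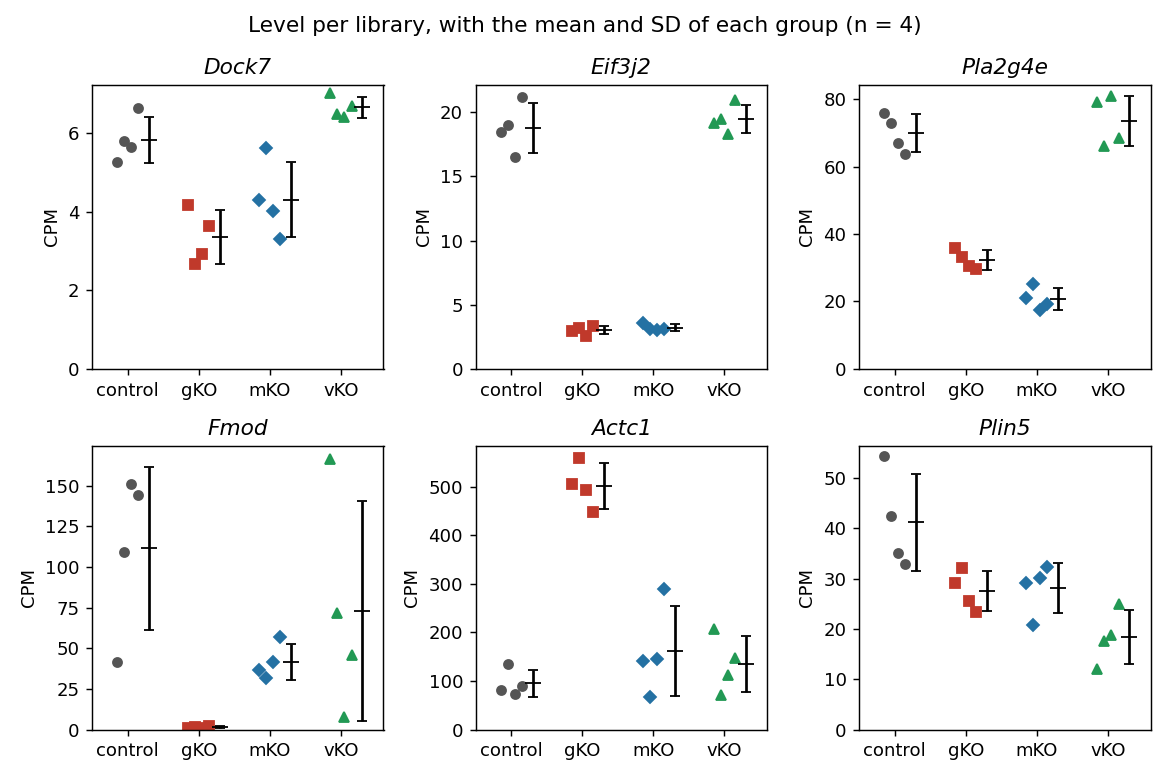
CPM of 6 genes in each of the 16 libraries, 1 point per library, with the mean and SD of each group beside its points (n = 4). Fmod averages 112 CPM in control and 1.5 in gKO, and Eif3j2 averages 18.8 CPM in control and 3.22 in mKO.

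The comparison of mKO with control asked what loss of Dock7 in the myofibre itself changed, and it includes the library labelled mKO replicate 2. Pla2g4e, a cytosolic phospholipase A2 gene, fell from 70 ± 5.56 to 20.7 ± 3.27 CPM (log2 fold change -1.76 ± 0.11 SE). Eif3j2 fell from 18.8 ± 1.94 to 3.22 ± 0.242 CPM (-2.54 ± 0.12 SE), while its near-identical copy Eif3j1 rose from 63.5 ± 3.88 to 96.8 ± 4.83 CPM (0.61 ± 0.09 SE). Nfatc2, a transcription factor activated by calcineurin, fell from 23.8 ± 1.69 to 9.76 ± 1.38 CPM (-1.29 ± 0.18 SE). Myl2, the slow and cardiac regulatory myosin light chain, fell from 6.32 ± 2.64 to 1.56 ± 0.953 CPM (-2.03 ± 0.49 SE). The edgeR adjusted p was 1.42e-07 for Pla2g4e, 2.18e-09 for Eif3j2, 0.00644 for Eif3j1, 0.00293 for Nfatc2 and 0.0477 for Myl2.

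Small increases in mKO included the ribosomal protein genes Rps13 (0.7) and Rps15a (0.67), the adropin precursor gene Enho (0.77), the histone H4 gene Hist1h4i (0.74), Ctxn3 (0.88), Nbdy (0.85) and the surface antigen gene Ly6c1 (0.6). With the length and GC offset, Ly6c1 (0.26, edgeR adjusted p = 0.248), Hist1h4i (0.36, adjusted p = 0.0726), Enho (0.61), Nbdy (0.58) and Rps15a (0.77) did not pass. Hist1h4i stood at 16 CPM in the library labelled mKO replicate 2, against 25.1 to 26.8 CPM in the other mKO libraries. Decreases included Gdpd3, a phosphodiesterase gene, from 8.25 ± 8.49 to 0.476 ± 0.0948 CPM (-4.1), with control replicates 3 and 4 at 0.856 and 0.938 CPM and the other controls at 15.8 and 15.4 CPM, Soga1 (-1.54, and -2.26 without the library labelled mKO replicate 2), the cell junction gene Cgnl1 (-1.17) and Cttnbp2nl (-1.12). Chrna1 (0.41), Chrne (0.06, -0.08 with the length and GC offset and -0.11 without control replicate 3), Musk (0.68) and Myog (0.53) did not pass the test in mKO, and Chrng was not tested. In edgeR's test 37 genes were higher and 224 lower than in control.

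Of the 39 lists, 6 passed camera with the preset correlation in mKO, 0 passed with an estimated correlation (0 at an unadjusted p of 0.05), and 0 passed fry (9 at an unadjusted p of 0.05). Cytoplasmic ribosomal protein genes were higher, with 61 of 63 positive, a median of 0.49, 3 called over all genes (Rps13, Rps15a and Rpl10) and 60 adjusted over the list alone (adjusted p = 3.97e-28, and adjusted p = 0.733 with an estimated correlation). Oxidative phosphorylation genes, such as Cox6a2 (0.37), Ndufa2 (0.49) and Cox7b (0.61), were higher as a list, with 38 of 39 positive and a median of 0.3 (adjusted p = 4.2e-08, and adjusted p = 0.745 with an estimated correlation). Glycolysis genes, among them Pgam2 (0.36), Gapdh (0.42) and Pgk1 (0.34), were higher with a median of 0.25 and 9 of 19 adjusted over the list alone (adjusted p = 0.00175, and adjusted p = 0.733 with an estimated correlation). Collagen and matrix genes, with Lamc1 (-0.63), Col5a1 (-0.72) and Lamb1 (-0.47), were lower, with 34 of 37 negative, a median of -0.51 and 6 adjusted over the list alone (adjusted p = 5.86e-07, and adjusted p = 0.733 with an estimated correlation). Tendon and spindle markers were lower (median -0.84; 2 adjusted over the list alone; adjusted p = 0.00475, and adjusted p = 0.733 with an estimated correlation), with Myh6 at -0.8, Myh13 at -0.72, Chad at -2.05, Thbs4 at -0.55 and Fmod at -1.42. Mitochondrial-genome transcripts were higher (median 0.24; adjusted p = 0.0258, and adjusted p = 0.745 with an estimated correlation), with mt-Rnr1 at 0.61, mt-Rnr2 at 0.4 and mt-Co2 at 0.31.

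With the length and GC offset, 5 of these 6 mKO lists stayed called. Their medians under the offset were 0.21 for ribosomal protein genes (adjusted p = 1.86e-19), 0.05 for oxidative phosphorylation (adjusted p = 0.049), 0.19 for glycolysis (adjusted p = 5.75e-06), -0.26 for collagen and matrix and -1.07 for tendon and spindle markers (adjusted p = 0.0073 for both). The mitochondrial-genome list turned to a median of -0.17 under this offset (adjusted p = 0.0975). With the offset and the library labelled mKO replicate 2 left out, the ribosomal and glycolysis lists stayed called, and the oxidative phosphorylation (0.0634), collagen and matrix (0.399) and tendon (0.191) lists were lost. The tendon list was lost without the library labelled mKO replicate 2 (adjusted p = 0.203), and the mitochondrial-genome list without control replicate 5 (0.117) or mKO replicate 4 (0.293). The count of 261 genes became 3807 without the library labelled mKO replicate 2, of which 1641 were higher and 2166 lower, and all 261 were among them. It became 17, 13 and 12 without mKO replicates 1, 3 and 4, and 21, 17, 44 and 124 without control replicates 1, 3, 4 and 5. Under the offset 53 genes were higher and 93 lower, 36.3% higher against 14.2% in the test without it. Of the 17 named genes called, 4 (Eif3j1, Nfatc2, Pla2g4e and Eif3j2) passed in each fit with 1 library left out.

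The vKO comparison asked what loss of Dock7 in motor neurons changed in the muscle they supply. Genes of lipid use fell: the lipid droplet protein gene Plin5 from 41.2 ± 9.63 to 18.3 ± 5.36 CPM (log2 fold change -1.17 ± 0.2 SE), the fatty acid binding protein gene Fabp3 from 420 ± 125 to 203 ± 44.4 CPM (-1.05 ± 0.22 SE), the acyl-CoA thioesterase gene Acot2 (-0.99) and the malonyl-CoA decarboxylase gene Mlycd (-0.58). Myl2, of slow fibres, fell from 6.32 ± 2.64 to 0.8 ± 0.115 CPM (-2.98 ± 0.53 SE). Among genes that rose, Amd1, which encodes adenosylmethionine decarboxylase of polyamine synthesis, went from 352 ± 43.7 to 710 ± 38.2 CPM (1.01 ± 0.17 SE), and Trdn, the triadin of the calcium release complex, from 451 ± 36.1 to 775 ± 18.8 CPM (0.78 ± 0.12 SE). Amd1 shares reads with its copy Amd2, so its level is uncertain. The edgeR adjusted p was 0.0351 for Plin5, Amd1 and Myl2, 0.0486 for Fabp3, 0.0419 for Acot2 and Mlycd, and 0.0202 for Trdn.

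Other genes that rose in vKO were the receptor subunit gene Neto2 (1.44), the transcription factor genes Tfcp2l1 (1.25) and Sp4 (0.85), Ankrd6 (1.23), the glucose transporter gene Slc2a3 (1.17), the Mediator kinase gene Cdk19 (0.95), Zfp74 (0.9) and the nuclear receptor gene Rora (0.75). Those that fell were the mitochondrial carrier gene Slc25a34 (-1.3), the small GTPase gene Rab15 (-1.49), Pdlim1 (-0.85) and the lymphocyte GTPase gene Gimap4 (-0.81). Musk, the receptor kinase of the neuromuscular junction, stood at 3.36 ± 0.572 CPM against 1.3 ± 0.276 and did not pass (1.37; edgeR adjusted p = 0.062). Chrna1 (-0.06), Chrne (-0.11) and Myog (-0.18) did not pass either, with signs that turned for Chrna1 with the replicate block (0.08) and without control replicate 5 (0.1) or vKO replicate 2 (0.02) or 4 (0.09), and for Chrne with the offset (0.02) and without vKO replicate 4 (0.08), and Chrng was not tested. In edgeR's test 34 genes were higher and 18 lower than in control.

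In vKO, 19 lists passed camera with the preset correlation, 15 lower and 4 higher, while 0 passed with an estimated correlation (4 at an unadjusted p of 0.05) and 4 passed fry. Fatty acid uptake and oxidation led, with 28 of 31 negative, a median of -0.4, 4 called over all genes and 21 adjusted over the list alone (adjusted p = 2.57e-15, and adjusted p = 0.183 with an estimated correlation). Oxidative phosphorylation genes, among them Cyc1 (-0.34), Ndufa9 (-0.34) and Sdhd (-0.31), were lower in 39 of 39 cases, with a median of -0.29 and 0 called (adjusted p = 9.99e-11, and adjusted p = 0.478 with an estimated correlation). Slow fibre genes were lower in 15 of 15 cases, with Myl2, Tpm3 (-0.46) and Casq2 (-0.74) and a median of -0.58 (adjusted p = 5.89e-06, and adjusted p = 0.234 with an estimated correlation). Immediate early and heat shock genes were lower, with Bag3 (-0.39), Cryab (-0.55) and Maff (-1.25), a median of -0.75 and 8 adjusted over the list alone (adjusted p = 5.92e-08, and adjusted p = 0.402 with an estimated correlation). Collagen and matrix genes were lower, with Col4a1 (-0.52), Col4a2 (-0.56) and Col15a1 (-0.54) and a median of -0.28 (adjusted p = 7.34e-06, and adjusted p = 0.478 with an estimated correlation). Genes of excitation-contraction coupling, with Trdn, Jph1 (0.64) and Camk2a (0.26), were higher, with 16 of 22 positive and a median of 0.12 (adjusted p = 0.0213, and adjusted p = 0.478 with an estimated correlation).

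Markers of other cells were lower as lists in vKO. Red blood cell markers, with Hbb-bs at 39.4 against 136 CPM and Hba-a1 at 31.7 against 110 CPM, had 5 of 6 lower adjusted over the list alone (median -1.71, adjusted p = 7.41e-06, and adjusted p = 0.386 with an estimated correlation). Endothelial markers, with Pecam1 at -0.34 and Cldn5 at -1.09, had 5 lower adjusted over the list alone (median -0.27, adjusted p = 0.00306, and adjusted p = 0.386 with an estimated correlation). Fibro-adipogenic markers, with Cd34 at -0.37 and Mgp at -0.72, were lower (median -0.33, adjusted p = 0.00323, and adjusted p = 0.478 with an estimated correlation), as were tendon and spindle markers, with Egr3 at -1.64 (median -0.5, adjusted p = 0.00765, and adjusted p = 0.474 with an estimated correlation). Neutrophil and mast cell markers, with Csf3r at -1.96 (median -0.63, adjusted p = 0.00924, and adjusted p = 0.422 with an estimated correlation), and macrophage markers, with Lyve1 at -0.8 (median -0.47, adjusted p = 0.0213, and adjusted p = 0.518 with an estimated correlation), were lower too.

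Further vKO lists passed with the preset correlation. Interferon response genes, with Ifit1 at -0.9 and B2m at -0.56, were lower (median -0.36, adjusted p = 0.000877, and adjusted p = 0.474 with an estimated correlation), as were mitochondrial-genome transcripts, with mt-Co3 at -0.41 (median -0.25, adjusted p = 0.00737, and adjusted p = 0.518 with an estimated correlation). Ribosomal protein genes, with Rpsa at -0.23 (median -0.14, adjusted p = 0.000877, and adjusted p = 0.673 with an estimated correlation), and brown and beige adipocyte genes, with Fabp3 (median -0.26, adjusted p = 0.0283, and adjusted p = 0.234 with an estimated correlation), were lower. Sex-chromosome genes, with Uty at 0.79 and Ddx3y at 0.53, were higher (median 0.51, adjusted p = 0.00284, and adjusted p = 0.183 with an estimated correlation). Muscle growth and AKT/mTOR genes, with Irs1 at 1.14 and the growth inhibitor Mstn at 0.71, were higher with 6 adjusted over the list alone (median 0.12, adjusted p = 0.0191, and adjusted p = 0.478 with an estimated correlation). Clock genes, whose members of smallest p were Rora, Npas2 (-1.41) and Hlf (0.92), were higher (median 0.26, adjusted p = 0.0346, and adjusted p = 0.386 with an estimated correlation). With the length and GC offset the adjusted p was 0.581 for ribosomal protein genes, 0.0753 for sex-chromosome genes and 0.418 for muscle growth genes.

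**Figure D3:**
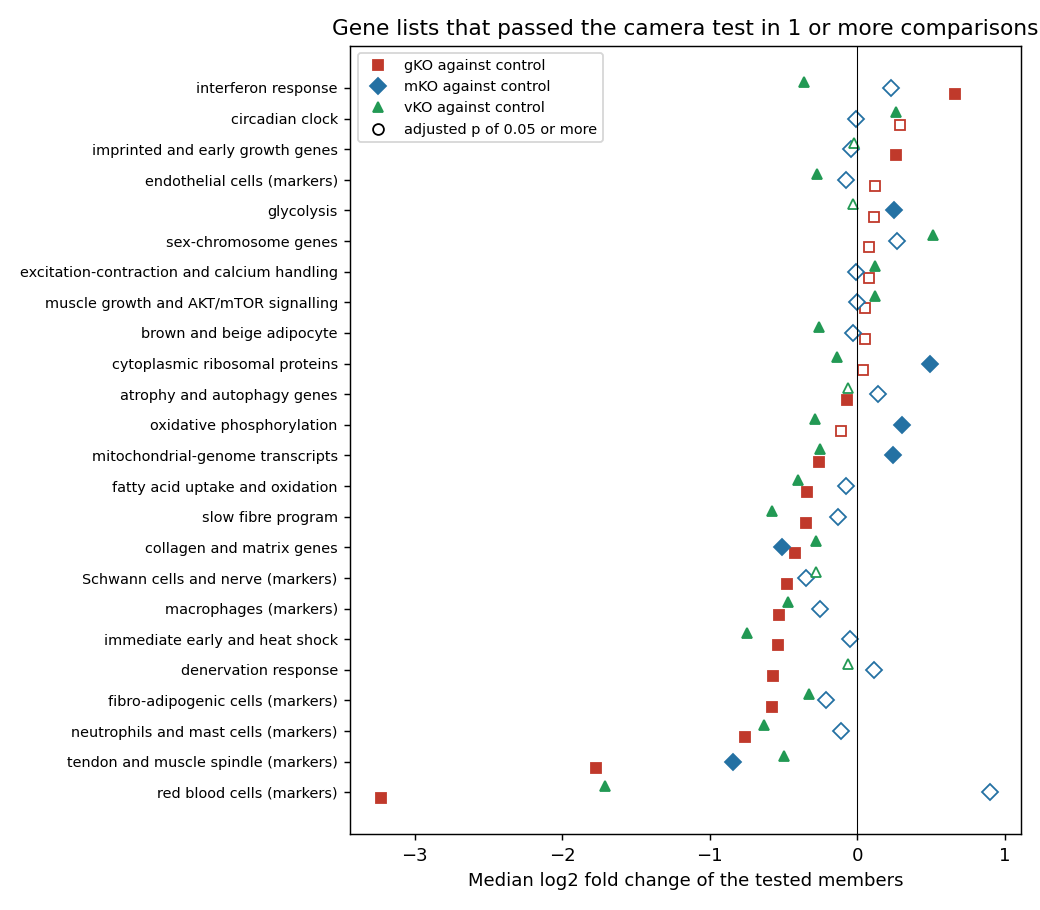
Median log2 fold change against control of 24 gene lists in gKO, mKO and vKO, 1 point per group and list, with no error bars, as each is a median over the list's measured genes. The tendon list lies at -1.77 in gKO and the ribosomal list at 0.49 in mKO.

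The 52 genes called in vKO became 1 without control replicate 3, 1 without control replicate 4, 4 without control replicate 5, and 7, 1, 14 and 12 without vKO replicates 1, 2, 3 and 4. With the library labelled mKO replicate 2 left out of the fit, 1768 genes were called. The single gene left without control replicate 3 or 4 or vKO replicate 2 was Gm6768, named after its values were seen. None of the 19 named genes called passed in every fit with 1 library left out, and none changed sign. Leaving out vKO replicate 4 ended the calls of the fibro-adipogenic (0.0712), neutrophil (0.0609), muscle growth (0.0502) and macrophage (0.264) lists. Without vKO replicate 1 the mitochondrial-genome (0.245), excitation-contraction (0.124) and brown adipocyte (0.0573) lists were lost, and without vKO replicate 3 the tendon (0.116), macrophage (0.0528) and clock (0.0745) lists. The brown adipocyte list was also lost with the library labelled mKO replicate 2 left out of the fit (0.103). Control replicate 1 decided the brown adipocyte (0.0785 without it) and clock (0.167) lists, control replicate 4 the clock list (0.0533), and control replicate 5 the macrophage (0.132) and excitation-contraction (0.0657) lists.

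The knockouts were then compared with each other. Between mKO and vKO, which share age and sex, Eif3j2 (log2 fold change -2.59), the predicted gene Gm3650 (-5.92) and Pla2g4e (-1.83) were lower in mKO, and Gm10605 (1.42), Ly6c1 (0.77) and the mitochondrial ribosomal protein gene Mrpl41 (1) were higher, with edgeR adjusted p between 1.59e-09 and 0.00396. In all, 1577 genes were higher and 1675 lower in mKO, whose values include the library labelled mKO replicate 2, and these 6 genes passed in each fit with 1 library left out. With the length and GC offset Ly6c1 was at 0.27 and did not pass (edgeR adjusted p = 0.135). With only the groups compared Ly6c1 and Mrpl41 did not pass (edgeR adjusted p = 0.0528 for both). The count of 3252 became 6473 without the library labelled mKO replicate 2, 1310, 956 and 1321 without mKO replicates 1, 3 and 4, and 2055, 1747 and 2052 without vKO replicates 1, 3 and 4. It was 1263 with the length and GC offset, 680 higher and 583 lower, so the balance of directions depended on the setting.

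In gKO against mKO, the natriuretic peptide receptor gene Npr1 (0.76), Irgm2 (1.94) and the semaphorin receptor gene Plxnd1 (0.8) were higher, and the Notch pathway ubiquitin ligase gene Mib1 (-1.11), Samd10 (-1.24) and the pseudogene Mid1-ps1 (-4.8) were lower, with 32 genes higher and 27 lower in edgeR's test. The 59 genes became 0 without gKO replicate 4 in edgeR's test (1176 at an unadjusted p of 0.05), 16 without gKO replicate 5 (14 higher and 2 lower), 11 (4 and 7) and 23 (7 and 16) without mKO replicates 1 and 3, and 2220 without the library labelled mKO replicate 2. DESeq2 was not run with libraries left out. With the gKO females only 55 were higher and 106 lower, and without a low-count filter 227 and 416, so the balance of directions is not settled. Without gKO replicate 4 the log2 fold change of Irgm2 was 0.82 (adjusted p = 0.451) and that of Mid1-ps1 -7.09 (adjusted p = 0.282), and neither passed. Without gKO replicate 5 they were 2.56, which passed, and -4.13 (adjusted p = 0.0816). With the females only Irgm2 was at 0.42 (adjusted p = 0.28). In gKO against vKO, the interferon-induced GTPase genes Tgtp2 (2.57) and Iigp1 (2.87) and the transcription cofactor gene Lbh (1.14) were higher, and Eif3j2 (-2.72), Gm3650 (-7.58) and Mib1 (-1.56) were lower, with 93 genes higher and 108 lower. Without gKO replicate 4 the log2 fold change was 1.23 for Iigp1, which did not pass (adjusted p = 0.372), 1.94 for Tgtp2 and -9.87 for Gm3650, and without gKO replicate 5 it was 3.61 for Iigp1 and -6.91 for Gm3650. With the females only it was 1.09 for Iigp1 (adjusted p = 0.0407) and 0.98 for Tgtp2, which did not pass (adjusted p = 0.0634). The 201 genes became 9 without gKO replicate 4, 43 without gKO replicate 5 (27 higher and 16 lower), and 128, 81 and 124 without vKO replicates 1, 2 and 4, and 2235 with the library labelled mKO replicate 2 left out of the fit. Both comparisons are confounded with age, and their fold changes with the sex term rest on the 2 male gKO libraries.

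Within gKO, 1 gene was higher and 14 lower in the 2 females than in the 2 males. Cyfip2, a gene of the WAVE complex that drives actin assembly, stood at 14.8 ± 1.42 CPM in females and 1.83 ± 0.0287 CPM in males (log2 fold change 3.02; edgeR adjusted p = 2.7e-05). The Y-chromosome genes had 0 counts in both females and were at least 536-fold (Eif2s3y), 464-fold (Ddx3y) and 99.6-fold (Kdm5d) higher in males, against a floor of 3 counts over the group. Xist, the RNA of the inactive X, was at 48.4 and 42.3 CPM in the females and 0 in the gKO males. The unnamed gene ENSMUSG00000120700.1 (2.99; adjusted p = 0.0766) and Sesn1 (0.78; adjusted p = 0.0891) did not pass edgeR's test. The 15 genes became 8 and 7 without gKO replicates 2 and 3, and 33 with the library labelled mKO replicate 2 left out of the fit. With the length and GC offset 5 were higher and 19 lower, 20.8% higher against 6.7%.

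Shared calls were counted among the 3 comparisons that use the same controls. In gKO and mKO together, 10 genes were lower in both and 0 higher in both, among them Eif3j2, Pla2g4e, Gm3650 and the nerve growth cone gene Dpysl3, the last pair named after their values were seen. Independent lists of these sizes would share 0.59 genes, groups simulated without effects against the same controls shared 0, and with a separate pair of controls for each comparison 4 were shared. Few genes pass where no gene is changed, so the simulated 0 does not show how many genes common controls would make lists of these sizes share. The directions in mKO include the library labelled mKO replicate 2. The log2 fold changes correlated at 0.489, against 0.4 in the simulation, with a covariance of 0.094 against 0.0339. For gKO and vKO 1 gene was shared in direction (Gm49708) and 1 was opposite (Mib1), with a correlation of 0.254 against 0.406 and a covariance of 0.0443 against 0.0341. For mKO and vKO 5 were shared in direction, 2 higher (Rora and the oestrogen receptor gene Esr1) and 3 lower (Myl2, Hsd17b4 and AI838599). Their correlation was 0.192 against 0.503 and their covariance 0.0267 against 0.0342, and 0 genes were shared in edgeR's test with a separate pair of controls for each comparison. Genes here outside the fixed rule were named after their values were seen.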

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

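Every test of an explanation in this part was chosen after the result was seen, and so was the count of other splits of the samples.

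The library labelled mKO replicate 2 lay apart from the other mKO libraries, with outlying levels of Hist1h4i (16 CPM), Soga1 (7.7), Musk (4.09), Lamc1 (94.3), Myh6 (11.4) and Thbs4 (68.6). Its second component (-1), its trend with transcript length (rho 0.3 against -0.53 to -0.48) and its trend with GC content (rho -0.36 against 0.08 to 0.14) were outlying too. A length and GC trend alone is argued against, as its distance to the other mKO libraries with the trend removed was 0.579, against 0.407 to vKO. A control or vKO library carrying the mKO label stays open: of 7 genes that part gKO and the other mKO libraries from control and vKO by over 1 log2 unit, it lay on the mKO side for 3 (Eif3j2, Gm14085 and Gm3650), and at gaps of 0.3 and 0.5 it did so for 7 of 90 and 6 of 32. For those 3 it held 3.14, 0 and 0.157 CPM, against at least 16.5, 1.36 and 5.7 CPM in the 8 control and vKO libraries. An unchanged label swap would not give such levels, but the rest of the 7 genes lay on the control and vKO side. Dock7 not deleted in that animal stays open as well, since Dock7 was at 5.61 CPM, inside the control range, but below the lowest control with the offset (2.21 against 2.38 log2 CPM). With the offset it also lay within the other mKO libraries (2.06 to 2.38 log2 CPM).

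Tendon markers were lower in gKO (median -1.77), and also as a list in mKO (-0.84) and vKO (-0.5). The 3 comparisons share the same controls, so these medians are not independent of each other. Less tendon in the tissue taken could account for the decrease in gKO. Across the 13 genes, the slope on the tendon axis within the other 12 libraries ran against the gKO log2 fold change (Spearman rho -0.85, Pearson r -0.85, permutation p = 0.00044), a relation across genes, which are not independent replicates. The axis is the mean of the other members of the list. Any cause that lowers these genes together could give this relation, so it does not single out less tendon. Myh6 (slope -0.36, log2 fold change -0.88) and Myh13 (-0.2 and -0.65) did not follow the axis and had small negative fold changes. The age of 2 months and the genotype cannot be told apart from each other, because no animal of that age carried intact Dock7. For 4 members (Fmod, Thbs4, Chad and Kera) every gKO library lay below every other library.

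The 10 genes called in both gKO and mKO were all lower. A length and GC trend is argued against as the whole cause, as 7 of the 10 stayed called in both with the offset. Linked variants of the mouse background stay open. The neighbours Dpysl3, Gm3650 and Eif3j2 on chromosome 18 made up all 3 pairs within 25 tested genes of each other, but their closeness prompted the count. Among the other 7 genes 0 pairs lay as close, though Pla2g4e and Gm14085 both lie on chromosome 2. A window this narrow cannot show linkage over longer stretches, so the 0 does not argue against linked variants. Reads shared between Eif3j1 and Eif3j2 stay open, since their summed level was 100 CPM in mKO against 82.3 in control, and reads with several places were not counted. An effect of losing Dock7, which both groups share, was not tested apart from these.

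For the 57 genes of gKO against control, 1 of 35 splits, the real one, called as many, and the highest other called 3. The same held for vKO against control (52 genes, highest other 15, 1 of 35) and gKO against vKO (201 genes, highest other 7, 1 of 35). A share of 1 of 35 is the smallest that these splits can give, and it was not adjusted over the 6 comparisons. Chance is therefore argued against for each of these taken alone, but it is not excluded. Other splits called as many genes for mKO against control (261 genes, highest other 1841, 5 of 35), mKO against vKO (3252 genes, highest other 4117, 2 of 35) and gKO against mKO (59 genes, highest other 2016, 5 of 35). These splits cannot decide on chance for them, so it stays open. In mKO against control and in gKO against mKO, splits that called several times the real count point to a structure of the samples. In these 3 comparisons the highest other split parted the library labelled mKO replicate 2 from the other mKO libraries. Such a split follows that structure and does not show what chance alone would call.

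A library far from the other 3 of its group was found for 33 of 394 values tested, where chance gives about 1 in 20, or 19.7. In gKO replicate 4 these were Iigp1 (53 CPM), Irgm2 (78.3), Gbp2 (13.2), Tnc (1.41) and Tpsb2 (1.98), and in gKO replicate 5 Kera (0.119) and Mib1 (35.4). Among controls they were Casq2 (82.4 CPM) and Aqp1 (457) in replicate 1, Hist1h4i (11.8) and Col5a1 (57.9) in replicate 3, Myh3 (6.57) and Slc25a34 (37) in replicate 4, and Csf3r (3.51), Mcpt4 (3.51), Pgam2 (1730) and Npas2 (1.19) in replicate 5. In mKO they were Eif3j2 in replicate 1 (3.58 CPM) and Myog in replicate 3 (4.33), besides those of the library labelled mKO replicate 2. In vKO they were Cyc1 in replicate 1 (420 CPM), Hlf in replicate 3 (34.6), and Maff (1.79), Rpl13a (0.818) and Cidea (0.613) in replicate 4.

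Differences between groups that passed edgeR's test numbered 3252 for mKO against vKO, 59 for gKO against mKO, 201 for gKO against vKO and 15 for gKO females against males. Reads outside the gene counts exceeded the highest control in several libraries. The share without a feature (highest control 2.4%) was 2.47% in gKO replicate 5, 2.61% in the library labelled mKO replicate 2, and 2.82, 2.49, 2.78 and 2.8% in vKO replicates 1 to 4. The ambiguous share (highest control 8.06%) was 8.54, 8.7 and 8.45% in gKO replicates 2, 3 and 5, and 8.4, 8.44 and 8.27% in mKO replicates 1, 3 and 4. The share without a unique place (highest control 11.46%) was 12.28, 12.52 and 14.41% in mKO replicates 1, 3 and 4.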

How the results depend on the processing

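The length and GC offset, alone and with the library labelled mKO replicate 2 left out, and the fits without that library for comparisons that do not involve mKO were chosen after the result was seen. Counts of genes called depended on the setting far more than directions did, and the causes were not tested. In gKO and vKO against control, the library labelled mKO replicate 2 is in neither group. Leaving it out there can act only through the shared fit, that is the spread, the filter and the normalization factors. The 57 and 52 calls of these 2 comparisons therefore depend on a library outside them. For gKO against control, 57 genes became 245 with DESeq2, 926 with limma voom, 644 without a low-count filter, 331 without the sex term, 130 at an adjusted p of 0.1, 525 with only the groups compared, 187 with gKO females only, 108 with the offset, 344 with the offset and mKO replicate 2 out, 447 with mKO replicate 2 out, and 4 to 43 with 1 library left out. For mKO, 261 became 1209 (DESeq2), 3731 (voom), 158 (RLE factors), 171 (library sizes without mitochondrial and top 20 genes), 1486 (no filter), 157 (mean CPM of at least 1), 411 (no sex term), 1334 (adjusted p of 0.1), 41 (at least 2-fold), 8 (only the groups compared), 146 (offset), 1780 (offset, mKO replicate 2 out) and 12 to 3807 (1 left out). For vKO, 52 became 683 (DESeq2), 1787 (voom), 138 (upper-quartile factors), 1211 (no filter), 131 (no sex term), 594 (adjusted p of 0.1), 14 (2-fold), 1414 (only the groups compared), 731 (offset, mKO replicate 2 out), 1768 (mKO replicate 2 out) and 1 to 44 (1 left out). For mKO against vKO, 3252 became 6442 (voom), 255 (2-fold), 13 (only the groups compared), 1263 (offset) and 956 to 6473 (1 left out). For gKO against mKO, 59 became 228 (DESeq2), 3166 (voom), 643 (no filter), 379 (no sex term), 154 (adjusted p of 0.1), 35 (2-fold), 4 (only the groups compared: Nmrk2, Thbs4, Fbxo32 and Fmod, of which Nmrk2 was named after its values were seen), 161 (females only), 859 (offset, mKO replicate 2 out) and 0 to 2220 (1 left out, 1176 at an unadjusted p of 0.05 in edgeR's test where 0). For gKO against vKO, 201 became 772 (DESeq2), 3111 (voom), 1378 (no filter), 1688 (no sex term), 684 (adjusted p of 0.1), 104 (2-fold), 1943 (only the groups compared), 385 (females only), 1180 (offset, mKO replicate 2 out), 2235 (mKO replicate 2 out) and 9 to 158 (1 left out). For gKO females against males, 15 became 49 (DESeq2), 41 (voom), 132 (no filter), 50 (only the groups compared), 24 (offset), 41 (offset, mKO replicate 2 out), 33 (mKO replicate 2 out) and 7 to 22 (1 left out).

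No pairing of the samples by replicate number was seen: over 19 same-numbered pairs the correlation of deviations ran from -0.19 to 0.09, 0 pairs exceeded 0.1, and in 2 of the 19 pairs the same-numbered library was the best match. The labels do not say what the numbers stand for, so a pairing is not excluded. With the replicate block the counts were 15 for gKO, 79 for mKO, 0 for vKO (edgeR, 1666 at an unadjusted p of 0.05, DESeq2 not run with the block), 8 for gKO against mKO, 23 for gKO against vKO and 8 for gKO females against males.

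Dock7 in gKO passed the threshold with DESeq2 (-0.83), voom (-0.84), no filter (-0.82), no sex term (-0.79), the offset with mKO replicate 2 out (-0.77) and mKO replicate 2 out (-0.84), and in mKO with voom (-0.51) and without mKO replicate 2 (-0.59), the lowest of -0.59 to -0.32 with 1 library left out. In vKO its direction turned with the offset, alone or with mKO replicate 2 out (-0.07 in both), and it did not pass. Lists called in gKO numbered 3 with an estimated correlation and 5 with fry. In mKO they numbered 2 with the offset and mKO replicate 2 out, 0 with an estimated correlation (0 at an unadjusted p of 0.05) and 0 with fry (9), and in vKO 0 with an estimated correlation (4) and 4 with fry. Without the sex term the Schwann cell (0.572) and slow fibre (0.38) lists were lost in gKO and the sex-chromosome list (0.637) in vKO, and with the replicate block macrophage markers (0.0588) in gKO and the mitochondrial-genome list (0.104) in mKO. The mitochondrial-genome list in mKO changed direction with the offset (adjusted p = 0.0975) and with the offset and mKO replicate 2 out (0.348). Genes shared in direction at an adjusted p of 0.1 numbered 42 for gKO and mKO, 17 for gKO and vKO and 46 for mKO and vKO, and 4, 0 and 0 with separate pairs of controls (edgeR). Of the genes that the fixed rule names and edgeR called, 14 of 17 in gKO, 8 of 17 in mKO and 19 of 19 in vKO did not pass with the replicate block, 5 in gKO with the females only and 5 with the males only, 13 in mKO with only the groups compared, 7 in mKO and 7 in vKO with the offset, and 4 in vKO without the sex term. No called gene that the text names by the fixed rule changed sign with 1 library left out.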

Other observations

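The tests of androgen signalling and of neighbouring genes were chosen after the result was seen, and the genes named in this part were chosen after their values were seen, except Arntl, Dbp, Amd1, Eif3j2, Npas2 and Gm3650, which the fixed rule names in at least 1 comparison.

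Components of the neuromuscular junction included 3 genes lower in mKO by edgeR's test, 6 lower and 1 higher adjusted over the list alone, of 27 measured. The organiser gene Agrn was at 19.8 ± 3.02 against 29.9 ± 2.59 CPM in control (log2 fold change -0.60, adjusted p = 0.0275), the calcium channel gene Cacna1s at -0.73 (adjusted p = 0.0477) and the sodium channel gene Scn4a at -0.81 (adjusted p = 0.0488). The list did not pass camera (adjusted p = 0.129), its median of -0.15 became 0.03 with the length and GC offset, and fry's unadjusted p for change in either direction was 0.000158. Fry's p of this kind was similar in mKO for cholesterol synthesis (0.000106), regeneration (0.000267) and DOCK family genes (0.000396), so it is not particular to junction genes. The 3 gene values are without the offset. These values include the library labelled mKO replicate 2. In gKO, the clock activators Arntl (-2.07) and Npas2 (-2.96, edgeR adjusted p = 0.0162) fell and the output factor Dbp rose by 1.12, while the clock list did not pass camera (adjusted p = 0.0743). The time of tissue collection was not given in the sources used here.

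The predicted gene Gm6768 stood at 4.35 ± 0.543 CPM in vKO and 0.17 ± 0.0814 CPM in control (log2 fold change 4.63, edgeR adjusted p = 0.000335). Genes called in gKO lay near each other more often than random genes, with 20 pairs within 25 tested genes against 5.64 (permutation p = 1e-04, the smallest that 10000 permutations can give, adjusted p = 0.00025). Without the 10 interferon GTPase genes called, which lie in clusters on chromosomes 3, 11 and 18, there were 7 pairs against 3.86 (permutation p = 0.093). Without Dpysl3, Gm3650 and Eif3j2 as well, which were noticed before the test, there were 4 against 3.38 (permutation p = 0.429). In mKO there were 152 pairs against 120.26 (permutation p = 0.0041) and in vKO 6 against 4.51 (permutation p = 0.296).

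A hypothesis is that androgen signalling was higher in the vKO males, noticed because Amd1 was higher in vKO and lower in gKO females. The androgen receptor gene Ar (0.64) and the oestrogen receptor gene Esr1 (0.73) were higher in vKO, both at an edgeR adjusted p of 0.0351. Esr1 was also called higher in mKO, so its rise is not particular to vKO. Of 9 autosomal genes lower in gKO females than males, 8 were positive in vKO, with a median of 0.64. Without Amd1 and Amd2, which share reads, the 7 left had a median of 0.45 and camera p = 0.034 with an estimated correlation, which is consistent with higher androgen signalling but may have other sources. In mKO the set of 9 gave a preset camera p of 0.351, while the 7 genes were not tested there, so the 2 groups are not compared alike. The log2 fold changes in vKO ran with transcript length (rho 0.36), and the set was not tested with the length and GC offset. No hormone was measured.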
